A study of Mus musculus x Rattus norvegicus with 2 samples.

How the data were processed

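The data were a pair of droplet single-cell RNA libraries of E20.5 lung, 1 control and 1 mutant, prepared with the 10x 3' v3 chemistry per the labels' protocols. The deposited matrices held the authors' counts of unique molecular identifiers (UMIs) per gene and barcode, as whole numbers with no scaling. Per the file headers, the control matrix came from Cell Ranger 6.0.1 and the mutant matrix from Cell Ranger 7.0.1. The genes of both files were those of a joint mouse and rat gene set with EGFP and Tomato sequences added, and builds mm10 and rn6 and Seurat 4.3 were named per the submitters' processing notes. Cell Ranger counts intronic reads by default from version 7 on, and the setting used for either file was not given in the sources used here. No Seurat output was used here.

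The matrices had 80802 features, 55403 of mouse and 25399 of rat. Mouse gene positions, exon lengths and intron lengths were read from the GENCODE vM21 annotation of mm10 by gene identifier, which gave a length to 99.5% of 55293 mouse symbols. No rat annotation was used here, so a rat gene took the intron length of the mouse gene of the same symbol, which reached 63.7% of rat symbols. Where features of a species shared a symbol, the feature with the most UMIs was used for the expression values.

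Barcodes were kept if they had at least 500 genes and at most 20% of UMIs from mitochondrial genes. A barcode was called mouse if at least 90% of its UMIs were from mouse genes, rat if at most 10% were, and mixed otherwise; mixed barcodes were left out of all cell comparisons. Doublets within a species were scored with Scrublet as run in Scanpy. Its automatic threshold called only 2 of the control mouse cells, so barcodes with a score of 0.2 or more were removed in both libraries, which took 154 control mouse cells (2.08%) and 356 mutant mouse cells (4.02%). Rat cells of the mutant library were fewer than 200 and were not scored.

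Mouse and rat cells were clustered apart, with the cells of both libraries together. Counts were scaled to a fixed total per cell and log-transformed, 2000 variable genes were chosen, and genes whose correlation with the cell cycle genes passed 0.15 were dropped along with sex-linked, globin, mitochondrial and ribosomal-RNA-like genes. Leiden clustering at resolution 1 used 30 principal components, 15 neighbours and random seed 1. Clusters took their class and type from marker lists, by the largest mean log2 fold against all other cells with at least 3 detected markers and a mean of at least 0.25. A cluster whose 10 top genes included more markers of another class was left unnamed. The mouse epithelium of each library was then clustered alone with 20 principal components and named by the same rule. Cell types named in this way are written with the ending "-like", since the names rest on marker RNA alone.

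For expression, UMIs were summed over the cells of a class in each library and given as counts per 1000000 mouse UMIs of those cells (CPM). A log2 difference was that of mutant over control after adding 10 CPM to both. Intervals are 95% and hold counting error only: exact Poisson for sums and CPM, exact Clopper-Pearson for shares of cells, and 1000 Poisson resamples for list medians. With 1 library per group no p-value, standard error or number of changed genes was computed, and no difference between the libraries had a replicate check. A UMI is a molecule, and the cells of a library are not replicates of its animal.

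Genes named from a comparison were chosen by size alone. They had at least 100 CPM in either library and at least 20 UMIs in the library where they were higher, and were ranked by the log2 difference. The rule took 10 on each side for the epithelial, endothelial and mesenchymal classes and 5 on each side for the AT1-like, AT2-like and immune comparisons. Mitochondrial, ribosomal protein, haemoglobin, red cell and sex-linked genes and unnamed gene models were left out of the ranking. Cmss1, one of the ribosomal-RNA-like genes dropped before clustering, was not left out. A further ranking kept genes with at most 10 kb of intron, because the log2 differences of all classes followed intron length. In the same way each gene's log2 difference was also taken relative to the median of genes of like intron length.

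The 35 gene lists, the cell type markers, the limits for barcodes and species, and the rule for named genes were fixed before the data were examined. The number of components and neighbours, the genes dropped before clustering, the doublet score limit and the rule for leaving a cluster unnamed were chosen while the clusters were built. A member was measured if it reached 10 CPM in either library, and lists with fewer than 3 measured members got no median. Values of a few single genes are not reported here. As a description of these libraries, each list median was placed as a percentile among 10000 random lists matched member by member on mean expression in 30 bins, and again among random lists matched on expression and intron length.

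For shares of cells with a UMI of a gene, each cell was thinned to 2000 UMIs, with cells below that depth left out, and the endothelial share was used as the background for epithelial genes. Thinning evened the total of each cell and not its split between genes of long and short introns. Counts that were 0 were given the upper limit that 3 counts allow.

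Alternatives fixed beforehand were species limits of 80% and 20% or 95% and 5%, at least 1000 genes, at most 10% mitochondrial UMIs, Leiden resolutions of 0.5 and 2, no doublet removal, joint clustering of both species on 15969 shared symbols, a pseudocount of 1 CPM, no CPM minimum, cells thinned to equal depth, and trimmed-mean scaling factors from edgeR. A limit of 32000 UMIs per barcode, lists restricted to genes with little intron, and values relative to genes of like intron length were added after the data were seen. Under the UMI limit the cells were clustered and named anew, so its values also hold changes in which cells were named. The edgeR factors shifted the log2 ratio of CPM by 0.25 in AT1-like, 0.27 in AT2-like and -0.23 in immune cells, and by less than 0.1 elsewhere.

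The computation was tested on simulated data. Poisson counts were drawn from the mean profile of both libraries for the control-against-mutant comparison of the mouse epithelial, endothelial and mesenchymal classes (9092, 9016 and 9267 genes), with 200 genes changed by 0.25-fold, 0.5-fold, 2-fold or 4-fold. All changed genes had the right sign with no intron trend in the simulation, and the largest median error was 0.05 log2. The 95% intervals held the true value for 95.6%, 94.6% and 94.9% of unchanged genes. Of 200 lists of 12 unchanged genes per class, 3%, 5.5% and 4.5% fell outside the central 95% of random lists. For changed genes with no trend, interval coverage was lowest at 88%, for epithelial genes changed 0.5-fold. The simulated genes were independent and Poisson, as the intervals assume, so values near 95% were largely built in. Spread between cells or animals and genes that vary together were not simulated. A simulated intron trend gave long-intron genes a median 0.80, 0.85 and 0.84 log2 above short-intron genes, and values relative to genes of like intron length removed it to 0.00 in each class. The simulated trend was a step at 100 kb, which was also an edge of the intron length bins, so its removal was built in. How well the relative values remove the gradual trend of these libraries was not tested.

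The work ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and Matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16.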

Results

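Lung cells were profiled from mouse-rat chimeric embryos at E20.5, in which mouse (C57BL/6) cells had contributed to the lung of a rat (SD) host. The control library came from a chimeric lung grown in a wild-type rat, and the mutant library from a lung grown in a rat lacking Nkx2-1, a transcription factor that the lung epithelium needs to form. There was 1 library per group, so no difference between the libraries had a replicate check. The control library held 11129 barcodes with 123047433 UMIs, of which 9021 (81.1%) were kept, with medians of 8416 UMIs and 3041 genes. The mutant library held 10918 barcodes with 103627303 UMIs, of which 8990 (82.3%) were kept, with medians of 10356.5 UMIs and 3401 genes. Barcodes with fewer than 500 genes numbered 1831 in the control and 1619 in the mutant library, and 565 and 1123 had over 20% mitochondrial UMIs. The median mitochondrial share of kept barcodes was 3.07% and 4.22%.

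The question asked of species was which of the cells came from the mouse and which from the rat host. Mouse cells made up 82.2% of kept barcodes in the control library (7414; 95% interval 81.4 to 83.0) and 98.5% in the mutant library (8854; 98.2 to 98.7). Rat cells made up 8.04% (725; 7.48 to 8.62) and 0.879% (79; 0.696 to 1.09), and mixed barcodes 9.78% (882; 9.17 to 10.4) and 0.634% (57; 0.481 to 0.821). Kept barcodes carried 18342364 rat UMIs in the control and 1814849 in the mutant library, beside 101540125 and 98494754 mouse UMIs.

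Nkx2-1, the gene deleted in the mutant host, had rat transcripts in the control library and almost none in the mutant library. Rat Nkx2-1 had 5044 UMIs in kept control barcodes (4906 to 5185) and 1 UMI in kept mutant barcodes (0.0253 to 5.57), and over all barcodes 5103 and 1. The 231 rat epithelial cells of the control library had 548 CPM of Nkx2-1 (531 to 565), with a UMI in 95.2% of them, and the mutant library had no rat epithelial cells in which to read it. Mouse Nkx2-1 (ENSMUSG00000001496; mm10 chromosome 12, 56531958 to 56536908) had 17888 UMIs in kept control barcodes and 9766 in kept mutant barcodes. In mouse epithelial cells it was at 496 CPM (488 to 504) in the control and 320 CPM (314 to 327) in the mutant library, a log2 difference of -0.61, and -0.04 relative to genes of like intron length. A UMI of mouse Nkx2-1 was found in 81.5% and 85.3% of these cells, and after thinning in 58.2% and 47.3%. The endothelial background was 6.08% and 2.36% unthinned and 2.73% and 0.829% thinned, and median depths were 10890 and 11892 UMIs in epithelial and 3618 and 7587 UMIs in endothelial cells. Thinning left out 161 control and 245 mutant epithelial cells, and 527 and 143 endothelial cells. Tags of 3' libraries can fall outside a deleted part of a gene, so the rat count alone did not test the deletion.

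All epithelial cells found in the mutant library were mouse. Mouse cells were 83.5% of epithelial cells in the control library (1165 of 1396; 81.4 to 85.4), where 231 were rat, and all 2133 in the mutant library, where 0 rat cells allowed a share of up to 0.141%. Rat transcripts of most epithelial genes were almost absent as well over all deposited barcodes. Rat Epcam, an epithelial adhesion gene, had 12737 UMIs in the control and 1 in the mutant library, rat Sftpc, a surfactant protein of AT2 cells, 56971 and 8, rat Krt8, a keratin of simple epithelia, 3886 and 0, and rat Scgb1a1, a club cell secretory protein, 11268 and 0. Rat Ager, a gene of AT1 cells, had 478 and 22 UMIs, of which rat pericyte-like cells held 10 and 8. All barcodes held 18910529 rat UMIs in the control and 1856112 in the mutant library. Most mouse epithelial cells of the control library were in clusters m10 (737), m9 (246) and m15 (178), and those of the mutant library in m11 (1028), m21 (655), m9 (278) and m15 (148). Clusters m10, m11 and m21 were mostly of 1 library each, so they may be that library and not a cell type.

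Rat cells were also fewer in the other classes of the mutant library, but the rat share of pericyte-like cells was not lower at the main species limits. Rat shares depended strongly on these limits. At 95% and 5%, mouse cells were 98.6% and 99.9% of mesenchymal cells, and rat cells were 3.26% (14 of 429) and 1.44% (3 of 208) of pericyte-like cells. Mouse cells were 99.3% of endothelial cells in the control (1627 of 1639; 98.7 to 99.6) and all 1952 in the mutant library, which allowed a rat share of up to 0.154%. In the mesenchyme they were 90.4% (4209 of 4655; 89.5 to 91.2) and 98.3% (4282 of 4355; 97.9 to 98.7), and among immune cells 85.6% (172 of 201; 79.9 to 90.1) and 94.7% (89 of 94; 88.0 to 98.3). Of alveolar fibroblast-like cells 6.62% were rat in the control library (184 of 2780) and 0 of 2514 in the mutant library (up to 0.119%), and of smooth muscle-like cells 17.7% (154 of 869) and 0 of 95 (up to 3.16%). Pericyte-like cells, which wrap capillaries, had a rat share of 15.01% (86 of 573; 12.2 to 18.2) and 18.6% (63 of 339; 14.6 to 23.1). The 79 rat cells of the mutant library were 63 pericyte-like, 10 myofibroblast-like, 5 macrophage-like and 1 erythroid-like, beside 179 AT2-like, 52 secretory-like, 184 alveolar fibroblast-like, 154 smooth muscle-like, 86 pericyte-like, 29 macrophage-like, 22 adventitial-like, 12 aerocyte-like and 7 erythroid-like rat cells in the control library.

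**Figure D1:**
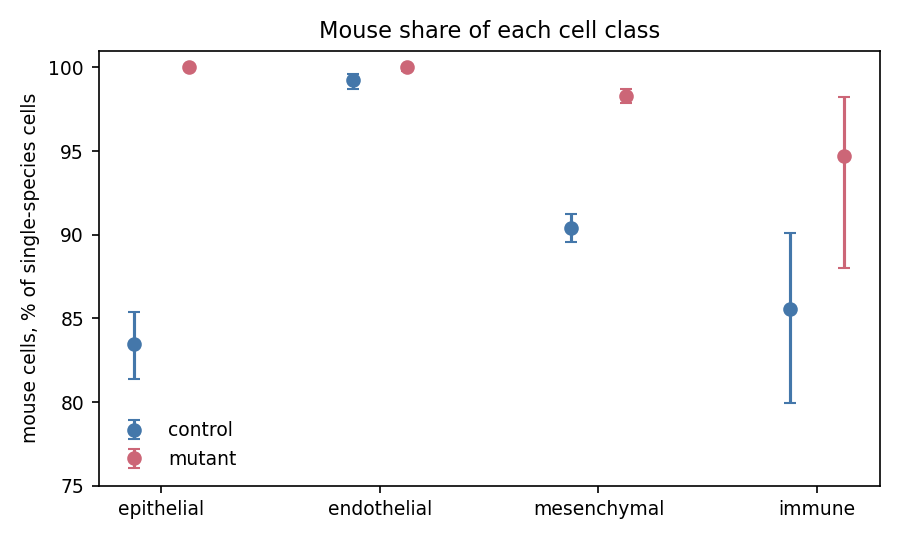
Mouse share of single-species cells (percent, axis from 75) per cell class in the control and mutant libraries, with exact binomial 95% intervals (counting error only, 1 library per group). All epithelial and endothelial cells of the mutant library were mouse.

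Endothelial mouse cells lay mainly in clusters m14 (780) and m8 (727) in the control and in m13 (1233), m24 (307) and m8 (152) in the mutant library. Mesenchymal mouse cells lay in m3 (1844), m2 (715), m6 (559) and m5 (487) in the control and in m7 (2049), m22 (1026), m6 (369) and m17 (345) in the mutant library. Immune mouse cells lay in m0 (163 and 58), and rat pericyte-like cells in r2 (86 and 1) and r13 (0 and 62). Clusters m2, m3, m5, m7, m13, m14, m22, m24, r2 and r13 were also mostly of 1 library, so shares per type set apart cells whose match between the libraries was not established. Clusters m6, m8 and m9 were shallow, with medians of 1839.5, 1547 and 1674.5 UMIs.

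The mouse epithelium held AT1-like, AT2-like and airway-like cells in both libraries. AT1 cells are the thin gas exchange cells and AT2 cells make surfactant. In the control library, AT1-like cells were 34.1% of 1165 epithelial cells (397; 31.4 to 36.9), AT2-like 12.4% (144; 10.5 to 14.4) and airway-like 14.2% (165; 12.2 to 16.3). In the mutant library they were 46.6% of 2133 (995; 44.5 to 48.8), 22.4% (478; 20.7 to 24.2) and 6.47% (138; 5.46 to 7.60). The rest, 459 and 522 cells, got no epithelial type name but stayed in the summed epithelial class. Among them were sub-clusters that scored best for fibroblast types: 189 control cells at a median of 2497 UMIs, and 42 mutant cells at 14826 and 302 at 1536. The 10 top genes of those 302 cells held only 1 mesenchymal marker. They also held Cryab, S100a6 and Lgals3, which were top genes of a mutant AT1-like sub-cluster, so the 302 cells may not be fibroblasts. The genes that define these types differed between the libraries, so the shares were not compared. Over 10 alternatives the shares ranged, for AT2-like cells from 12.4% to 27.8% in the control and 20.7% to 34.4% in the mutant library, and for AT1-like cells from 28.9% to 45.5% and 37.0% to 58.7%.

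Ager, a receptor abundant in AT1 cells, had a UMI in 78.4% of mouse epithelial cells in the control and 93.8% in the mutant library, and after thinning in 59.9% and 78.2%. The endothelial background was 9.22% and 25% unthinned and 3% and 8.24% thinned, at the depths and numbers of cells given for Nkx2-1. Hopx, a homeobox gene of AT1 cells, had a UMI in 68.8% and 83.8%, and after thinning in 41.6% and 63.5% (thinned background 1.55% and 6.08%). Epcam was found in 88.6% and 78.8%, and after thinning in 78.1% and 40.0% (2.27% and 0.442%). Sftpc was found in 96.5% of epithelial cells of both libraries, and after thinning in 82.3% and 75.3%, where the thinned endothelial background of free RNA was 46.5% and 48.5%. Sox9, a transcription factor of distal tip progenitors, was found in 49.3% and 19.3%, and after thinning in 14.9% and 3.97% (1.91% and 1.71%). Genes with at most 10 kb of intron took 61.5% of epithelial UMIs in the control and 48.7% in the mutant library. Thinned shares of such genes may therefore be lowered in the mutant library.

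Expression in mouse cells was compared to ask how donor cells differed between a lung grown in a host with Nkx2-1 and one grown without it. In all mouse classes, genes with long introns were higher in the mutant library. In epithelial cells the median log2 difference was -0.56 for genes with up to 2 kb of intron, -0.42 for 10 to 20 kb, 0.31 for 50 to 100 kb and 1.31 for more than 200 kb. Across genes the Spearman correlation of log2 difference and intron length was 0.523 in epithelial, 0.632 in endothelial and 0.578 in mesenchymal cells, and genes are not independent replicates. Genes with at most 10 kb of intron took 61.5% of epithelial UMIs in the control and 48.7% in the mutant library, 54.4% and 36.1% of endothelial, and 55.0% and 40.6% of mesenchymal UMIs. The files also came from different Cell Ranger versions, so list medians are followed by the median relative to genes of like intron length, marked by the word relative. Pairs of CPM values are control before mutant, and a single value beside a gene or list is a log2 difference of mutant over control.

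**Figure D2:**
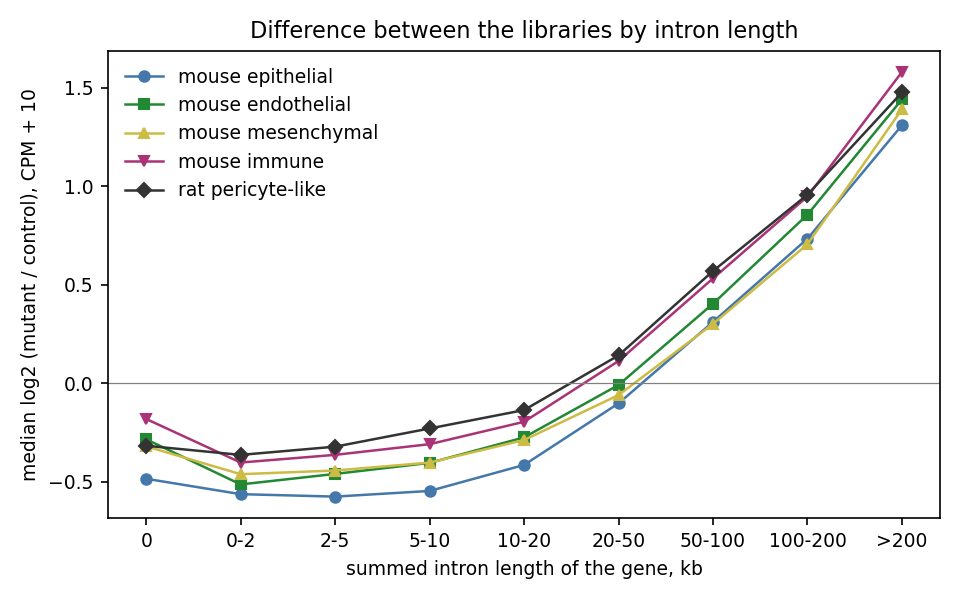
Median log2 difference (mutant over control) of genes binned by summed intron length in kb, 1 line each for mouse epithelial, endothelial, mesenchymal and immune cells and rat pericyte-like cells. Genes with more than 200 kb of intron were higher in the mutant library in all of them.

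In mouse epithelial cells, genes of mature alveolar cells were higher and genes of dividing cells lower in the mutant library. The match of the named cell types of this class between the libraries was not established, so its differences may include those of make-up. Lyz2 (ENSMUSG00000069516; mm10 chromosome 10, 117277331 to 117282321), a lysozyme of mature AT2 cells, was at 6.12 CPM in the control (5.31 to 7.01) and 1739 CPM in the mutant library (1723 to 1754), a log2 difference of 6.76. Lyz1, a related lysozyme, was at 6.92 and 1753 CPM (6.70), Scd1 (ENSMUSG00000037071; chromosome 19, 44394455 to 44407879), a fatty acid desaturase, at 5.55 and 841 CPM (5.77), and Chil1, a chitinase-like secreted protein, at 0.835 and 335 CPM (4.99). The other genes highest by the size rule were Cmss1 (5.96, with 302868 bp of intron), the calcium-binding S100g (4.85), the phosphodiesterase Pde4d (4.67), complement gene Hc (4.62), surfactant protein Sftpd (4.59) and the AT1 gene Rtkn2 (4.57). Cmss1 had been dropped before clustering as ribosomal-RNA-like, so its values here and in the other classes may not be those of the gene. Among genes with little intron the highest also included the AT1 water channel Aqp5 (4.42 and 332 CPM, 4.57), the secreted Retnla (4.20), Msln (3.87), Scgb1a1 (3.58) and Lcn2 (3.33).

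The lowest gene was the histone gene Hist1h2ap, at 1885 CPM in the control (1871 to 1900) and 2.36 CPM in the mutant library (1.82 to 3.01), a log2 difference of -7.26. It was followed by histone H2ac8 (-5.02), the mitotic ubiquitin enzyme Ube2c (523 and 7.04 CPM, -4.97), the growth factor Mdk (675 and 12.2 CPM, -4.95) and the imprinted fetal RNA H19 (1317 and 51.2 CPM, -4.44). Pclaf (-4.396) and Birc5 (-4.23) of dividing cells, linker histone H1f5 (-4.11), chromatin protein Hmgn2 (-3.88) and heat-shock gene Hspa1a (461 and 24.3 CPM, -3.78) came next. Histone genes were also among the top genes of control sub-clusters of 125 and 88 epithelial cells, beside ribosomal-RNA-like genes. Whether the lower histone RNA was that of dividing cells was not tested.

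Genes of surfactant and of the lamellar body, its storage organelle, were higher in the mutant epithelium in 11 of 12 cases, with a median log2 difference of 1.46 (1.44 to 1.49). Sftpc was at 31524 and 65473 CPM (1.05), Sftpb at 783 and 2445 (1.63), Sftpa1 at 506 and 2825 (2.46), and the gastric protease gene Pgc was lower (-0.31). The median was at percentile 100 of random lists (relative 1.92). AT1 markers were higher in 9 of 10 cases, with a median of 2.41 (2.39 to 2.43; percentile 100, relative 2.64), such as Ager (622 and 3283 CPM, 2.38) and Hopx (331 and 1070 CPM, 1.66), and only the tight junction gene Cldn18 was slightly lower (-0.10). In AT2-like cells alone the AT1 median was 0.04 (relative -0.06). Genes of neonatal AT2 maturation were higher in 9 of 10 cases (median 3.35, relative 3.84; Cxcl15 279 and 2700 CPM, 3.23). Lipid synthesis genes were higher in all 12 (1.19, relative 1.40; Fasn 101.1 and 199 CPM, 0.91; but -0.13 in AT1-like cells alone), and cholesterol synthesis genes in 8 of 12 (0.23, percentile 85.3, relative 0.63). The AT1-like lipid median was 0.02 in thinned cells, 0.06 with trimmed-mean scaling and 0.21 over genes with little intron, so its direction did not hold.

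Genes of the distal tip progenitors, from which alveoli form, were lower in 7 of 9 cases in the mutant epithelium (median -0.61, percentile 17.1, relative -0.23), with Sox9 at 122 and 31.3 CPM (-1.68), Id2 at 366 and 191 CPM (-0.90) and the growth factor receptor Fgfr2 higher (0.81). Lung epithelial transcription factors had a median of -0.08 (relative -0.08, 6 of 17 higher), from Hopx (1.66) and Cebpa (1.19) down to Sox9, with Foxa2, a partner of Nkx2-1, at 98.3 and 35.1 CPM (-1.26). Ciliated cell markers were higher in 10 of 10 cases (1.27, relative 1.39; Tmem212 2.60, Foxj1 0.00), and the 3 measured secretory markers had a median of 0.78 (relative 1.199; Scgb3a2 1233 and 1093 CPM, -0.17). Of the neuroendocrine markers only Calca was measured (9.82 and 40.5 CPM).

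Cell division genes were lower throughout the mutant epithelium. All 14 genes of the G2 and M phases were lower, with a median of -2.93 (-2.99 to -2.88; percentile 0, relative -2.94), from Ube2c to the spindle motor Kif11 (-2.12), and Mki67, a marker of cycling cells, was at 235 and 9.26 CPM (-3.67). All 12 S phase genes were lower (-2.22; -2.27 to -2.16; relative -1.92), with the replication helicase gene Mcm3 at 84.4 and 2.77 CPM (-2.89). Mki67 had a UMI in 53.6% and 6.28% of epithelial cells, and after thinning in 24.9% and 1.48%, with Top2a, a mitotic topoisomerase, in 30.4% and 2.70%. No class was free of dividing cells and fit to give a background for these genes.

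Among the stress and signal lists of the epithelium, hypoxia genes were higher in 9 of 12 cases (0.50, percentile 97.9, relative 0.89), with the vessel growth factor Vegfa at 84.6 and 363 CPM (1.98) and the glycolytic Ldha lower (-0.97). Genes of the unfolded protein and heat-shock responses had a median of -0.64 (10 of 11 lower), but it lay at percentile 14.2 of random lists and 51.2 of intron-matched lists (relative -0.22, 7 of 11 lower). Immediate early genes, which tissue dissociation induces, had a median of -0.18 (relative -0.01). Growth arrest and p53 genes had a median of -0.69 but relative -0.13 (5 of 10 higher; Cdkn1c 1456 and 345 CPM, -2.05; Cdkn1a 0.86), lung signals and receptors -0.23 (relative 0.06, 7 of 13 higher; Notch1 -1.43), and extracellular matrix genes 0.24 (relative 0.10, 8 of 13 higher; Col6a1 3.02). Interferon response genes had 0.24 (relative 0.82) with 4 measured, antigen presentation genes 0.60 (relative 1.18) with 5, mitochondrially encoded genes 0.36 (relative 0.85) with 8, and cardiac genes 0.86 (relative 1.24) with 3. Y-linked genes had 0.34 (relative 0.76) with 3 measured, and the red cell, platelet and thyroid lists had fewer than 3 measured members in epithelial cells.

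AT1-like cells (397 control, 995 mutant) had more RNA of their own markers in the mutant library, as a group. Of the control cells 165 were in 2 sub-clusters with scores of 0.57 and 0.47, while 4 of 5 mutant sub-clusters scored 1.08 to 1.47. Those 2 control sub-clusters had at most 1 AT1 marker among their 10 top genes, as did mutant sub-clusters of 211, 120 and 217 cells. The match of the groups was therefore not established. All 10 AT1 markers were higher (2.53, relative 2.83), with Aqp5 at 11.1 and 747 CPM (5.16) and Ager at 1180.5 and 7064 CPM (2.57). The same markers had named these cells. Sftpc was at 15099.9 and 5167 CPM (-1.55) and Sftpb at 429.9 and 96.1 CPM (-2.05), but the surfactant list as a whole lay among random lists (-0.41, percentile 27.1, and 54.4 of intron-matched lists; relative -0.24, 7 of 12 lower). The surfactant median was 0.33 in cells of at most 32000 UMIs, so its direction did not hold. Those cells were clustered and named anew, which gave 259 control and 772 mutant AT1-like cells. A change in which cells were named may therefore be a part of this. The AT2 maturation list was lower (-0.97, percentile 0.78, relative -0.54, 4 of 6 lower), but 0.46 in cells of at most 32000 UMIs, while matrix genes were higher in 11 of 12 cases (0.45, relative 0.75), led by the basement membrane collagens Col4a2 (2.06) and Col4a1 (1.58). Of the genes chosen by size, Cmss1 (6.57), Msln (4.42) and Ptprm (4.33) were also among the highest, and Hist1h2ap (-6.83), Ube2c (-5.06), H2ac8 (-4.86), Mdk (-4.64) and H19 (-4.63) the lowest. G2 and M phase genes had a median of -3.14 (relative -3.11).

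AT2-like cells (144 control, 478 mutant) were richer in surfactant, lipid and sterol synthesis RNA in the mutant library, as a group. The control cells were 1 sub-cluster, and 145 control and 178 mutant cells in sub-clusters that also scored best for AT2 were left unnamed, so the match of the groups was not established. Many of the surfactant genes were also among the markers that had named these cells. The highest genes were Lyz2 (2.24 and 3724 CPM, 8.25), Lyz1 (7.55), Scd1 (9.40 and 1855 CPM, 6.59), Chil1 (6.01) and Pde4d (5.74), and the lowest Hist1h2ap (-7.98), H2ac8 (-5.56), Mdk (-5.41), Pclaf (-5.05) and Ube2c (-4.88). Surfactant genes were higher in 11 of 12 cases (1.72, relative 2.32), lipid synthesis genes in 12 of 12 (1.85, relative 2.04) and cholesterol synthesis genes in 11 of 12 (0.93; 0.82 to 1.06; relative 1.47), led by Hmgcs1, which makes a sterol precursor (37.8 and 182 CPM, 2.01). AT2 maturation genes had a median of 3.97 (relative 4.62), tip progenitor genes -0.80 (relative -0.28; Bmp4 -1.77, Sox9 -1.59) and G2 and M phase genes -3.16 (relative -2.97).

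**Figure D3:**
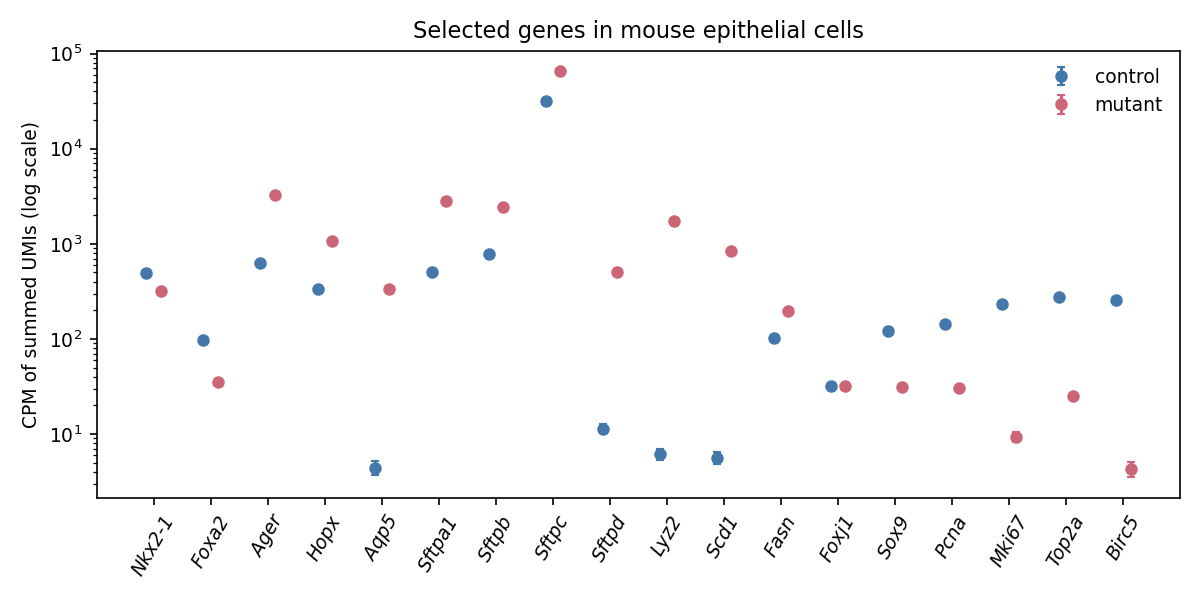
CPM of 18 genes (log axis) in summed mouse epithelial cells of the control and mutant libraries, 1 point per library, with exact Poisson 95% intervals (counting error only). Lyz2, Scd1 and Aqp5 were higher and Mki67 and Birc5 lower in the mutant library.

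In mouse endothelial cells (1627 control, 1952 mutant), genes of the aerocytes, the gas exchange capillary cells, and of the interferon response were higher in the mutant library. The named types of the class differed in number, with 0 and 307 aerocyte-like cells (all in m24), 727 and 166 lymphatic-like cells and 781 and 1253 general capillary-like cells. Of the lymphatic-like cells, 727 and 152 lay in the shallow cluster m8, whose 10 top genes held only Ccl21a of the lymphatic markers. Clusters m13, m14 and m24 were mostly of 1 library. The match of these types was therefore not established, and differences of the class may include those of make-up. All 7 measured aerocyte markers were higher, with a median of 1.43 (1.34 to 1.54; percentile 100, relative 1.37). Car4, a carbonic anhydrase of these cells, was at 2.23 and 118 CPM (3.39), Prx at 26.4 and 123 CPM (1.87) and the receptor Kdr at 538 and 672 CPM (0.32). All 10 interferon response genes were higher (1.28; 1.18 to 1.37; percentile 100, relative 1.38), with Isg15 at 10.9 and 94.5 CPM (2.32), Oasl2 at 10.2 and 91.7 CPM (2.33) and Ifitm3 at 667 and 1199 CPM (0.84). General capillary markers were higher in 6 of 9 cases (1.05, relative 0.27), such as the lipase anchor Gpihbp1 (213 and 717 CPM, 1.70), while Aplnr was at 302 and 142 CPM (-1.03).

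The largest endothelial differences by size were those of long-intron and heat-shock genes. Cmss1 (6.37), Galnt2l (0 and 453 CPM; at least 2303-fold), the synapse scaffold Gphn (4.74), Pde4d (4.60), Arl15 (4.57), Hdac9 (4.55), Prkg1 (4.398), Aff3 (4.36), Maml2 (4.06) and Lrmda (3.91) were highest, all of them genes with very long introns. Galnt2l was at 0 CPM in the control here and in the mesenchymal and immune classes, and at similar levels in the mutant library. Its values may therefore reflect how the files were counted and not a difference between cells. Chaperone genes Hspa1a (2400.02 and 72.1 CPM, -4.88), Hspa1b (-4.42), Hsph1 (-3.47) and Hspd1 (-2.38) were lowest with Hist1h2ap (-4.05), Mdk (-2.67), Phlda1 (-2.38), Sec61g (-2.15), Ccn1 (-2.11) and Gadd45g (-2.09). Hist1h2ap lay well below the S phase median of this class (-1.17), so its difference did not follow that of division genes in size. With little intron, Car4 was highest, with Ly6c1 (2.496), the fatty acid carrier Fabp4 (2.45), Ly6a (1.80), Gpihbp1 and the alveolar capillary gene Tmem100 (1.50).

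Division and sterol genes were lower in mutant endothelial cells. The 14 genes of the G2 and M phases were all lower, by less than in the epithelium (-0.76; -0.81 to -0.72; percentile 0.13, relative -0.52), from Ube2c (-1.34) to Kif11 (-0.07), and the 12 S phase genes too (-1.17, relative -0.89). Mki67 had a UMI in 41.1% and 24.0% of endothelial cells, and after thinning in 32.8% and 16.0%. All 11 cholesterol synthesis genes were lower (-0.95; -1.03 to -0.84; percentile 0, relative -0.68), led by Fdps, which makes farnesyl units (-1.79). Arterial markers had a median of -0.15 (relative -0.04, 3 of 8 higher; Gja4 -1.09) and venous markers 0.50 (relative 0.22, 4 of 5 higher; Vegfc 1.04). The arterial median was 0.19 over genes with little intron and the venous median -0.05 in thinned cells, so neither direction held. Antigen presentation genes were higher in 6 of 6 cases (0.45, relative 0.92; H2-K1 0.89). Lists named for epithelial cells were higher too, with AT1 markers at a median of 1.35 (relative 1.48) and surfactant genes at 0.52 (relative 0.80). Mouse Ager was at 0.111 and 0.382 UMIs per endothelial cell and at 0.105 and 0.304 per rat cell, about the level of background RNA.

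In mouse mesenchymal cells (4209 control, 4282 mutant), matrix genes were higher in the mutant library. The named types of this class differed in number as well, with 715 and 95 smooth muscle-like, 1 and 1026 myofibroblast-like and 487 and 276 pericyte-like cells. Clusters m2, m5 and m22 were mostly of 1 library. The match of these types was therefore not established, and differences of the class may include those of make-up. All 16 extracellular matrix genes were higher (0.69; 0.67 to 0.70; percentile 99.8, relative 0.55 with 13 of 16 higher), with fibronectin Fn1 at 557 and 2720.1 CPM (2.27), elastin Eln at 1423 and 5286 CPM (1.89), the elastic fibre gene Mfap4 at 4039.6 and 6582 CPM (0.70) and the collagen Col1a2 lowest (0.13). Alveolar fibroblast markers were higher in 9 of 10 cases (1.22, relative 0.57 with 8 of 10 higher), from Inmt (2.22) to Wnt2 (-0.25), and myofibroblast markers in 7 of 10 (0.78, relative 0.94; the growth factor receptor Pdgfra 180 and 379 CPM, 1.03). Smooth muscle markers were lower in 8 of 8 (-0.46, percentile 14.0, relative -0.77; Acta2 1731 and 655 CPM, -1.39), and pericyte markers were near 0 (0.02, relative 0.08, 5 of 10 higher; Trpc6 1.72).

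Mesenchymal division and sterol genes were lower in the mutant library, and immediate early genes higher. All 14 genes of the G2 and M phases had lower values (-2.42; -2.46 to -2.37; percentile 0, relative -2.30), as did all 12 of S phase (-1.68, relative -1.52). Mki67 was found in 38.2% and 11.1% of mesenchymal cells (medians of 8880 and 10907 UMIs), and after thinning, with 412 and 359 cells left out, in 21.8% and 3.62%. All 11 cholesterol synthesis genes were lower (-1.04; -1.13 to -0.98; relative -0.84), led by Fdps (-1.94). Immediate early genes were higher in 11 of 13 cases (1.01, relative 1.48), with Btg2 at 511 and 1962 CPM (1.92) and Fos at 903 and 2149 CPM, while the heat-shock genes of that list were lower (Hspa1a -4.35). Lung signals and receptors had a median of -0.17 (relative -0.12, 6 of 16 higher), with Fgf10, the growth factor of distal buds, at 58.9 and 189 CPM (1.53) and the hedgehog target Gli1 lower (-0.61).

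By size, Hs6st3, a heparan sulfate enzyme (10.3 and 1385 CPM, 6.10), Cmss1 (5.87), Galnt2l (0 and 460.2 CPM; at least 6013-fold), Nrxn3 (5.23), Egfem1 (19.6 and 1003 CPM, 5.10), Prkg1 (4.56), Gphn (4.16), Kcnq5 (4.02), Rora (4.02) and Nlgn1 (3.99) were highest in mesenchymal cells, again all with very long introns. As in the endothelial class, the values of Galnt2l may reflect how the files were counted. The lowest were Hist1h2ap (-5.98), Hspa1a (-4.35), Hspa1b (-4.32), H2ac8 (-4.23), Ube2c (-3.50), Pclaf (-3.27), Id1 (-3.15), H1f5 (-3.09), Birc5 (-3.08) and Stmn1 (-3.07). With little intron, the lectin Clec3b (2.80), the membrane protein Ifitm1 (2.79), Btg2, the RNA-binding Zfp36 (1.73) and the lipid carrier Apoe (573 and 1890.4 CPM, 1.70) were among the highest.

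**Figure D4:**
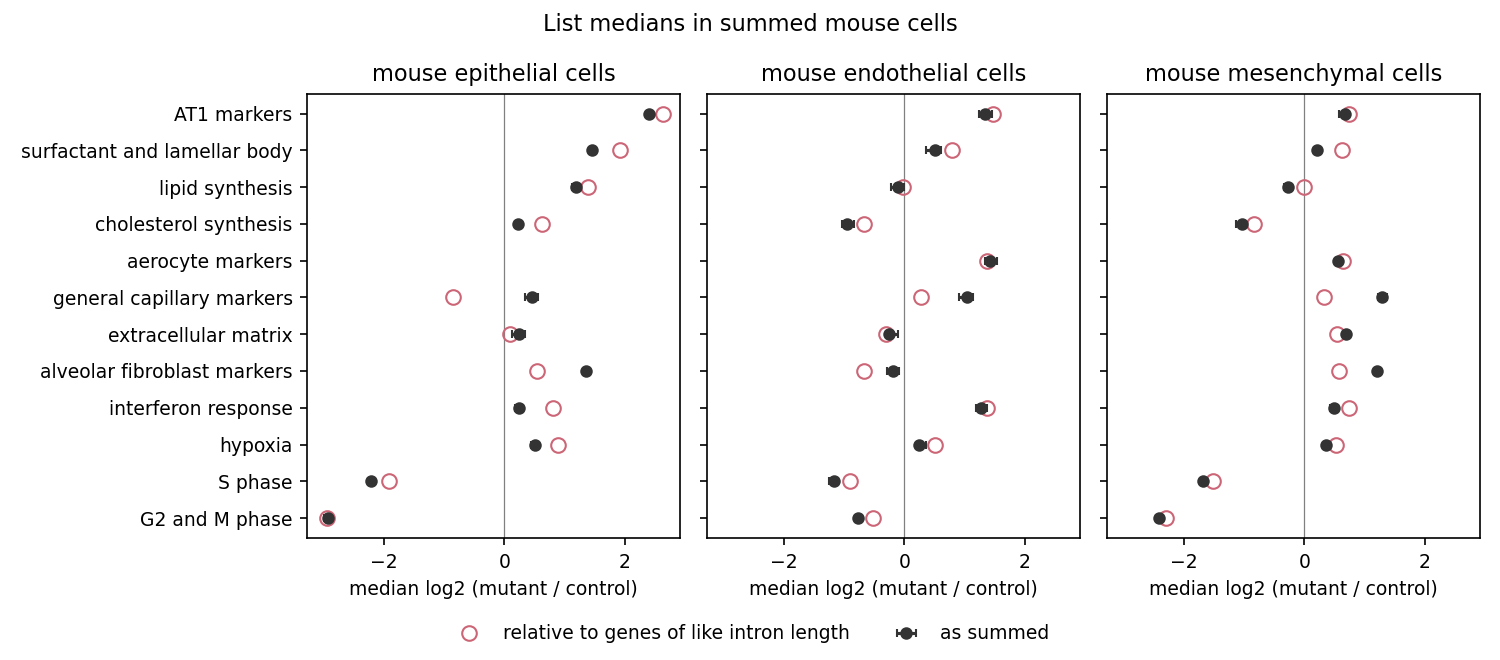
Median log2 difference (mutant over control) of gene lists in mouse epithelial, endothelial and mesenchymal cells, with 95% intervals from Poisson resampling (counting error only); open circles are medians relative to genes of like intron length. Genes of S, G2 and M phases were lower in all 3 classes.

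Mouse immune cells were few and differed in make-up, with 163 macrophage-like and 3 B-like of 172 control cells and 58 macrophage-like and 22 B-like of 89 mutant cells, so the differences of this class include those of make-up. The mast cell proteases Cma1 (0 and 751 CPM; at least 565-fold) and Tpsb2 (0 and 411 CPM; at least 309-fold) and the antibody gene Igkc (5.21) were highest with the long-intron genes Cmss1 (5.72) and Galnt2l (0 and 352 CPM; at least 265-fold). Genes of complement-making macrophages were lowest with Hist1h2ap (-5.30): C1qa (745 and 14.1 CPM, -4.97), Pf4 (-4.68), C1qb (-4.61) and C1qc (-4.56). S phase genes had a median of -1.38 (relative -1.203) and G2 and M phase genes -1.27 (relative -1.24). Interferon response genes were higher in 7 of 8 cases (0.77, relative 0.70), while AT1 markers (1.90, relative 1.91) and surfactant genes (1.24, relative 1.40) were higher too, the latter list with Lyz2 (0.22) and Ctsh (-0.79), which macrophages express themselves, and background RNA was not excluded.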

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

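All tests of explanations in this part, and their limits, were chosen after the differences had been seen.

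The EGFP sequence added to the mouse genes was the one measurement in the files that no planned comparison had used. It had a UMI in 99.6% of mouse cells of the control library and 97.9% of mouse cells of the mutant library, at 77.1 and 42.1 UMIs per 10000 mouse UMIs. In rat cells it was found in 72.0% and 38.0%, so the share of cells with a UMI did not set the species apart. Mouse cells held a mean of 97.45 and 46.7 EGFP UMIs and rat cells 2.29 and 0.494, and Tomato had 0 UMIs. The lower level in the mutant library was not tested.

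Some gene lists went in opposite directions in different cell types. Cholesterol synthesis genes were higher in AT2-like cells of the mutant library (0.93, relative 1.47) and lower in endothelial (-0.95, relative -0.68) and mesenchymal cells (-1.04, relative -0.84), differences of the medians of 1.88 and 1.97 log2. Neonatal AT2 maturation genes were higher in AT2-like cells (3.97, relative 4.62) and lower in AT1-like cells (-0.97, relative -0.54), a difference of 4.94, but the AT1-like value was 0.46 in cells of at most 32000 UMIs, so its direction did not hold. The same list was higher in endothelial (1.03, relative 1.49) and mesenchymal cells (0.89, relative 1.31), with 4 measured members in each and background RNA not excluded, with differences of 2.002 and 1.86 against AT1-like cells. The causes of these opposite directions were not tested.

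Genes with long introns were higher in the mutant library in every mouse class. In rat pericyte-like cells, genes with over 100 kb of intron were also higher than those with up to 10 kb, by 1.42 log2 (1.33 to 1.47; 1055 and 2428 genes, with a length for 92.7% of the measured genes). A difference of this size in cells of both species is consistent with intronic reads counted for the mutant file and not for the control file. More nuclear RNA in the mutant cells, read by Malat1 alone, was argued against as the whole cause, since mesenchymal cells matched on the share of Malat1, a nuclear RNA, in 20 bins kept 80.5% of the difference in long-intron share (79.2 to 82.2, from resampled cells; 9.65 percentage points unmatched, 7.77 matched). The difference was 5.39 to 12.3 points in 17 bins and only 1.06 to 2.55 in the 3 bins with the least Malat1, so a part from nuclear RNA stays open. The intron setting was not given in the sources used here, so the host genotype and other differences between the libraries stay open and untested.

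Cell cycle genes were lower in the mutant library in mouse epithelial (-2.72), mesenchymal (-2.18) and endothelial cells (-0.91). Intron counting alone was argued against by the 11 members with little intron, whose median closest to 0 among these classes was -0.64 (-0.72 to -0.58), in endothelial cells. Very deep barcodes in the control library were argued against by cells of at most 32000 UMIs, whose median closest to 0 was -0.82 (-0.89 to -0.79; 26 genes). In rat pericyte-like cells the same genes had a median of -0.70 (-0.80 to -0.51, 21 of 24 lower), so a difference between the whole animals, such as stage, may contribute. Both libraries were labelled E20.5. The rat cells of the libraries lay almost all in different clusters, so their match was not established. Mouse pericyte-like cells had a larger difference, -1.56 (26 of 26 lower). The host genotype differed in the same way as the animals did, and it stays open and untested.

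Rat cells of the mutant library were mostly pericyte-like (63 of 79). A first test asked whether other rat cells were hidden among mixed or removed barcodes. At the control ratio of 603 other epithelial, endothelial and mesenchymal rat cells to 86 pericyte-like cells, 442 would have been due, and 80 further mutant barcodes had over 10% rat UMIs, 18.1% of that number. This test decided nothing, since it assumed the control ratio, and if all 80 were other cells the pericyte-like share would be 39.6%. Further tests took parts of the question. Hidden rat epithelial cells were argued against, as rat epithelial markers per rat UMI over all mutant barcodes were at 0.256% of their control level (0.117 to 0.486). The markers included Nkx2-1 itself, with 5103 of 35786 control marker UMIs, so a part of this may follow from the genotype. Of the other markers, Epcam had 12737 and 1 UMIs, Krt8 3886 and 0, and Cdh1 1019 and 5. Rat epithelial cells without RNA of these markers would have been missed. That most rat cells in mixed mutant barcodes were of other kinds was argued against by pericyte markers at 80.1% of their level in rat pericyte-like cells (77.0 to 83.3; 8873 and 11074.5 CPM of rat UMIs). Alveolar fibroblast markers in the same mixed barcodes were at 1240 CPM, against 625 in rat pericyte-like cells, so some hidden rat cells of other kinds stay open. Whether the host genotype or the course of this chimera left these cells was not tested and stays open.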

How the results depend on the processing

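The UMI limit, the lists of genes with little intron and the values relative to genes of like intron length were chosen after the data had been seen. No paired analysis was possible because each group had 1 library of its own embryo and the labels pair nothing. The planned comparison of expression in rat cells, with its alternatives, was not run, as no rat class had 100 cells in both libraries. For the rat pericyte-like cells looked at afterwards, cholesterol synthesis genes ranged from -1.66 with a pseudocount of 1 CPM to -0.93 with little intron, and pericyte markers from 0.67 relative to genes of like intron length to 0.87 with a pseudocount of 1 CPM. Of the main results 117 alternative values stayed within the counting interval, 75 moved past it and 0 changed sign. Most of these were shares of cells or UMI counts, which cannot be negative, so the lack of sign changes tells only of the list medians. Of 913 alternative values of the other list medians 410 stayed within it, and 72 in 46 of 137 lists changed sign, 20 of them relative to genes of like intron length. The main value was at least 0.5 in size in 12 of these and at least 1 in size in 1 of them, general capillary markers in mesenchymal cells, -0.016 with no CPM minimum against 1.30. Of single genes 180 stayed, 328 moved and 0 changed sign. These genes had been chosen for large differences, so a change of sign was unlikely from the start. The mouse share of mutant epithelial and endothelial cells was 100% in every alternative. Extracellular matrix genes had no little-intron value, with only 2 such members. The cause of these movements was not tested.

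With species limits of 80% and 20%, the control mouse share was 83.4% of barcodes, 79.3% of epithelial, 88.4% of mesenchymal and 79.4% of immune cells, and 97.7% of mutant mesenchymal cells; mutant AT1-like cells were 38.7%. With 95% and 5% it was 79.6% of barcodes, 94.6% of epithelial, 99.8% of endothelial and 98.6% of mesenchymal control cells and 99.9% of mutant mesenchymal cells; control AT2-like cells were 27.8%. With at least 1000 genes the control share was 83.2% of barcodes and 98.7% of endothelial cells, AT1-like cells were 38.0% in control and 43.2% in mutant epithelium, and AT2-like cells 23.1% and 34.4%. With at most 10% mitochondrial UMIs, 79.5% of control epithelial cells were mouse, AT1-like cells were 45.5% and 58.7%, and AT2-like cells 17.9% and 32.7%.

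At Leiden resolution 0.5, AT2-like cells were 23.7% in control and 29.7% in mutant epithelium. At resolution 2, 80.3% of control epithelial cells were mouse, AT1-like cells were 38.3% and 42.0%, mutant AT2-like 27.3% and control airway-like 16.4%. Without doublet removal mutant AT1-like cells were 43.6% and control AT2-like 21.4%. With joint clustering, 94.0% of control mesenchymal cells were mouse, AT1-like cells were 30.5% and 37.1%, AT2-like 18.0% and 30.5%, and mutant airway-like 7.62%. Thinned cells gave AT1-like shares of 38.9% and 50.3%, and the UMI limit 28.9% and 37.0%, with 14.8% for control AT2-like cells.

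For list medians, a pseudocount of 1 CPM gave 1.49 for epithelial surfactant genes, 2.44 for AT1 markers and -4.23 for G2 and M phase genes, 1.60 for endothelial aerocyte markers, and -0.84 and -3.03 for endothelial and mesenchymal G2 and M phase genes. Thinned cells gave in the same order 1.51, 2.38, -3.04, 1.57, -0.88 and -2.37, and 0.62 for mesenchymal matrix genes. The UMI limit gave 1.93, 1.88, -2.88, 1.59, -0.71 and -2.47, and genes with little intron 1.97, 2.72, -3.32, 2.13, -0.45 and -2.59. TMM scaling gave 1.49 for surfactant genes and 2.44 for AT1 markers. Relative to genes of like intron length, surfactant genes had 1.92, AT1 markers 2.64, endothelial and mesenchymal G2 and M phase genes -0.52 and -2.30, and matrix genes 0.55.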

Other observations

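All comparisons in this part were chosen after the data had been seen.

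Pericyte-like cells were the type with the most rat cells among those with cells of both species in both libraries (86 and 63 rat, 487 and 276 mouse). The pericyte markers had also named these cells. Rat cells lay in r2 (86 and 1) and r13 (0 and 62), and mouse cells in m5 (487 and 103) and m26 (0 and 173). Their match between the libraries was not established, so the values below may include a difference in which cells were named. Cholesterol synthesis genes were lower in the mutant library in all 12 cases in rat cells (-1.28; -1.51 to -0.95; relative to genes of like intron length -1.20, 11 of 12 lower) and in all 11 measured in mouse cells (-1.17, relative -1.15). Pericyte markers were higher in 10 of 10 cases in rat cells (0.86, relative 0.67 with 9 of 10 higher), led by Higd1b, a mitochondrial gene of pericytes (223 and 1361 CPM; 2.56), and in 9 of 10 in mouse cells (0.78, relative 0.78). Smooth muscle markers had medians of -0.75 in rat (relative -0.84) and 0.23 in mouse cells (relative 0.45), and interferon response genes were higher in 5 of 5 cases in both (0.64 and 0.95, relative 1.00 and 1.30). G2 and M phase genes had medians of -0.61 and -1.95 (relative -0.56 and -1.69), and S phase genes -0.75 in rat cells (relative -0.56). The rat cells were fewer than the 100 per library set for a planned comparison.

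Mouse pericyte-like cells of the mutant library also carried heart muscle RNA. All 6 measured cardiac genes were higher (2.87, relative 3.21), with the atrial myosin light chain Myl7 at 0 and 264 CPM, the heart myosin Myh6 at 0 and 171 CPM and the troponin Tnnt2 at 13.2 and 178 CPM. Whether these were heart muscle cells of pulmonary veins or cells of the heart left on the tissue was not analysed here.

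Y-linked RNA was found in mouse cells of both libraries and differed in rat cells. Mouse cells had UMIs of Eif2s3y in both libraries (3280 and 3637) and almost none of Xist, the RNA of the inactive X (21 and 9). Rat Eif2s3y had 0 UMIs in 725 control rat cells and 61 in 79 mutant rat cells, and rat Kdm5d 0 and 29. Rat Ddx3y had 11 UMIs in control and 0 in mutant rat cells. The sex of the embryos was not given in the sources used here.

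Barcodes with both species gave an estimate of multiplets, 26.5% of barcodes over 5000 UMIs in the control library (23.8 to 29.3) and 9.19% in the mutant library (5.45 to 14.5). The estimate took such barcodes for random pairs of cells, which was not tested. At the main species limits, mixed control barcodes had a median of 6200.5 UMIs, below the 8270.5 of mouse and 9843 of rat barcodes. Some of them may therefore not have been pairs of cells. Barcodes over 32000 UMIs were 7.02% and 1.08% of those kept. Free RNA was present in both libraries, with Sftpc in 82.4% and 88.7% of endothelial cells at 260 and 331 CPM.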
